A study of Mus musculus and Rattus norvegicus with 18 samples.

How the data were processed

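RNA from mouse primary tubular epithelial cells (TECs) and from the rat kidney fibroblast line NRK49F was sequenced in 18 libraries, 3 per group in 6 groups. The groups were control, TGF-β and TGF-β with narciclasine in each cell kind. Narciclasine is an alkaloid of daffodil bulbs that binds the ribosome and slows protein synthesis. Per the labels, cells were starved of serum for 6 h, received 20 nM narciclasine 2 h ahead of TGF-β where it was given, and were held with 5 ng/ml TGF-β for 24 h. The libraries were made from poly(A) RNA and sequenced on an Illumina instrument. The groups hold no library with narciclasine alone, and cell kind and species go together, so neither can be separated from the other.

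The authors provided 1 table per cell kind, and its deposited values are counts per gene and library, not normalised. The submitters' processing notes name HISAT2 2.1.0, featureCounts and DESeq2 without saying in which step each served. They also name the mouse build mm10 for all 18 samples. The rat table carries rat Ensembl gene identifiers, so the rat build and annotation release behind it are not given in the sources used here. The mouse values covered 22322 genes and the rat values 22050 genes, and 4451 and 6903 of these had no count in any library. A total of 20 mouse symbols and 133 rat symbols stood for more than 1 identifier, and these entries were kept apart. Among the rat entries, 2 symbols read as dates and 18 entries with a mean of at least 100 counts had 9 counts identical to those of another entry. Mouse coordinates are those of the GRCm38 annotation. No rat coordinates were used here.

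Each cell kind was fitted separately with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 13244 genes in TECs and 11444 in NRK49F, and libraries were scaled by TMM factors. The quasi-likelihood test with robust dispersions compared TGF-β with control, TGF-β with narciclasine against TGF-β, and TGF-β with narciclasine against control, with all 9 libraries of a cell kind in 1 fit. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene counted as changed at an adjusted p under 0.05. Fold changes are log2 values from that fit with their standard errors. Expression levels are CPM values, which are counts divided by the scaled total of the library, with the SD over the 3 libraries of a group. The p-values measure the spread between these samples, which the series describes as biological replicates. Whether the TEC replicates came from separate animals or isolations was not established here. NRK49F is a single line, so its p-values do not measure the spread between animals. Where every library of a group was at 0, the fold is a bound computed with 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and bounds cover counting error only.

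The question of the design is whether narciclasine changes the response to TGF-β. With no library with narciclasine alone, a changed response cannot be told apart from an effect that narciclasine would have without TGF-β. A gene was called moved back when TGF-β changed it and narciclasine changed it the other way. The term names directions only. Both comparisons share the TGF-β libraries, so the count was set beside the count for independent changes and beside 20 simulations with no narciclasine effect. The difference between the cell kinds was tested as a cell-by-treatment interaction in 1 edgeR fit of all 18 libraries. It used genes whose symbol matched between the tables and occurred once in each. Symbol matching stands for orthology there.

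A set of 34 gene lists was tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2. Lists with at least 5 tested members were used, which were 34 in TECs and 30 in NRK49F. Some genes belong to more than 1 list, so the list calls are not independent of each other. Camera asks whether a list moved more than the other genes did. It was run again with a correlation estimated from the libraries for each list, and fry was run beside it, which asks only whether members move 1 way on balance. The adjusted p of a list is that of camera, and the adjusted p of a gene is that of edgeR. Members that changed are also counted with p-values adjusted over the list alone.

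Genes were named by a rule. It took preset genes of fibrosis and epithelial state, among them Ccn2, Col1a1, Col1a2, Col3a1, Fn1, Acta2, Tagln, Vim, Cdh1, Smad7 and Postn. It added the 7 genes each way with the largest changes among those with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the libraries of the groups, without clone-style symbols. From each list it added up to 4 changed members with the largest changes. For TGF-β with narciclasine against control only the preset genes and list members were taken. For the difference between cell kinds, the preset genes and the 5 largest interactions each way were taken. The rule, the lists, the comparisons and all other settings named next, except those said to be added, were fixed before the data were examined.

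Total counts per library ran from 16652016 to 25192716 in TECs and from 14695732 to 18463855 in NRK49F. The common biological coefficient of variation was 0.0296 in TECs and 0.0812 in NRK49F. The steps were tested on simulated data of the same depth and spread. With 50 genes changed at each size, edgeR recovered 98% of genes changed 1.5-fold in TECs and 82% in NRK49F, and 64% and 16% of genes changed 1.2-fold. It made 10 false calls among 13122 simulated genes in TECs and 12 among 11325 in NRK49F. The interaction test recovered 76% of genes changed 1.5-fold. Camera found the 1 raised list in each cell kind with 0 false calls. The simulated genes were drawn independently of each other, so this does not test list calls among correlated genes.

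The alternatives were RLE size factors, upper-quartile factors, total counts, other filters, a term for the replicate number, limma-voom, the DESeq2 1.42.0 Wald test, fits of only the 6 libraries compared, an added minimum of 1 for the absolute log2 change, and leaving out each library in turn. Leaving out the replicate 2 libraries of NRK49F, summing or leaving out entries that share a symbol, and total counts for the interaction were added after the data were seen. No library was left out of the results reported here.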

Results

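Polyadenylated RNA was measured in mouse primary TECs, cultured from kidney tubules, and in the rat kidney fibroblast line NRK49F, each as control cells, with TGF-β and with TGF-β plus narciclasine. Each group had 3 libraries. Control TECs had 16652016, 25192716 and 19900401 counts, TECs with TGF-β had 22680497, 17217290 and 22867693, and TECs with TGF-β and narciclasine had 22732412, 18836468 and 18432332. Control NRK49F cells had 15503662, 14818642 and 15242924 counts, those with TGF-β had 16309795, 14695732 and 14981306, and those with TGF-β and narciclasine had 17499698, 18463855 and 15274783. Replicate 2 stood apart from replicates 1 and 3 in each NRK49F group. The spread over counting error was 7.58 to 19.9 times for pairs of NRK49F libraries with replicate 2 and 2.39 to 3.34 times for the other pairs, against 1.84 to 3.70 times in TECs. Transcripts encoded by mitochondria made up 4.32 to 4.60% of counts in control TECs, 5.36 to 5.75% with TGF-β and 3.94 to 4.02% with added narciclasine. In NRK49F they made up 2.85 to 3.01%, 2.13 to 3.77% and 2.03 to 2.75%.

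The first comparison asks what TGF-β did to tubular cells. Inflammatory genes rose in TECs and the genes of the cell division cycle fell, each as a list with an adjusted p of 0.00471 with an estimated correlation. Matrix genes rose too, but their list calls ended with an estimated correlation (adjusted p = 0.0725 for collagens, 0.161 for matrix glycoproteins and 0.0592 for crosslinking genes). Fn1 (ENSMUSG00000026193), which encodes fibronectin, went from 3228 ± 65.8 to 16480 ± 562 CPM (SD, n = 3 per group), a log2 change of 2.35 (SE 0.0259, adjusted p = 1.49e-26). Csf2, the cytokine GM-CSF, rose the most of the genes named for this comparison, by 6.06 (SE 0.0664, adjusted p = 3.17e-43), from 2.78 ± 0.319 to 188.2 ± 7.05 CPM. Mki67 (ENSMUSG00000031004), a marker of dividing cells, fell from 432.5 to 63.9 CPM, a log2 change of −2.76 (SE 0.0328, adjusted p = 5.21e-42).

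All 40 tested cell cycle and proliferation genes fell, by a median of −2.23 log2 units (adjusted p = 1.29e-20; adjusted p = 0.00471 with an estimated correlation). Cdc20, which activates the anaphase-promoting complex, changed by −2.86 and Ccna2, cyclin A, by −2.85. Of 35 inflammatory and NF-κB target genes, 29 rose and 1 fell, with a median of 2.05 (adjusted p = 1.49e-11; adjusted p = 0.00471 with an estimated correlation), and 29 and 2 did so adjusted over the list alone. Tnf rose by 3.9, the chemokine Ccl7 by 4.55 and Nos2, the inducible nitric oxide synthase, by 4.37. Macrophage and leukocyte markers were higher beside them, 11 of 14 tested up and 1 down (12 and 1 adjusted over the list alone) with a median of 1.12 (adjusted p = 0.0201; adjusted p = 0.108 with an estimated correlation). The summed level of these markers was 49.7 CPM in control cells and 80.5 CPM with TGF-β. TGF-β and SMAD target genes rose, 22 of 28 up and 3 down with a median of 0.93 (adjusted p = 1.88e-07; adjusted p = 0.00919 with an estimated correlation). Smad7, the inhibitory SMAD, rose by 1.60 (SE 0.0457) and the cytokine Il11 by 3.36 (SE 0.0395), while Id2, an inhibitor of DNA binding, fell, with a log2 change of −2.56 (SE 0.102). Ribosome biogenesis and nucleolar genes fell, 30 of 32 down and none up with a median of −0.43 (adjusted p = 4.3e-08; adjusted p = 0.0123 with an estimated correlation).

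Of 19 collagen genes 18 rose and none fell, with a median of 1.72 (adjusted p = 4.3e-08; adjusted p = 0.0725 with an estimated correlation). Col1a1 (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042, plus strand) rose by 2.55 (SE 0.047), from 35.2 to 206.5 CPM, Col1a2 by 1.77 and Col7a1 by 2.76. Col3a1 rose by 0.42 (SE 0.0995, adjusted p = 0.000263). Matrix glycoproteins rose, 18 of 25 up and 4 down with a median of 0.89 (adjusted p = 0.000108; adjusted p = 0.161 with an estimated correlation), among them Tnc, tenascin C, by 2.43. Matrix crosslinking, processing and proteolysis genes rose, 22 of 30 up and 8 down (adjusted p = 0.00184; adjusted p = 0.0592 with an estimated correlation), among them the collagenase Mmp13 by 2.99 and the gelatinase Mmp9 by 3.81. Acta2, smooth muscle actin, rose by 0.66 (SE 0.0283), Tagln by 0.73, Ccn2 by 0.92 and Postn, periostin, by 0.96 (SE 0.186). The contractile list as a whole was not called (adjusted p = 0.0829), with 14 of 26 members up and 7 down, or 15 and 7 adjusted over the list alone. Cdh1, E-cadherin, rose by 0.45 (SE 0.0212, adjusted p = 1.16e-21). Vim, vimentin, rose by 0.10 (SE 0.0237, adjusted p = 0.000319). Scaled by total counts alone its change was −0.031 (adjusted p = 0.241, over alternatives 9.66e-05 to 0.241).

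**Figure D1:**
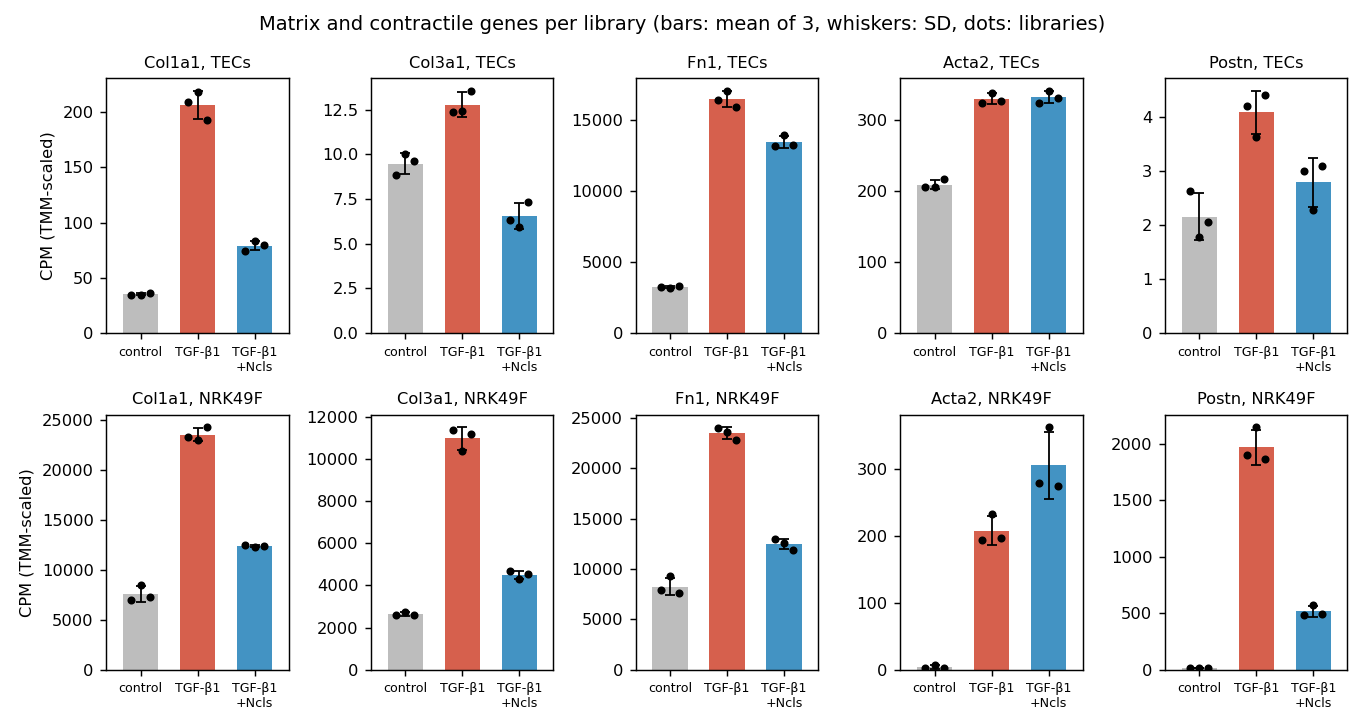
Expression in CPM of Col1a1, Col3a1, Fn1, Acta2 and Postn in control, TGF-β and TGF-β with narciclasine libraries of TECs and NRK49F. Bars are means of 3 libraries, whiskers are SD and dots are single libraries, and the Fn1 bar of TECs goes from 3228 to 16480 and then 13440 CPM.

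Other lists were called in TECs as well, and none of these calls held with an estimated correlation. Cholesterol synthesis genes fell, 24 of 28 down and 2 up with a median of −0.44 (adjusted p = 1.04e-06; adjusted p = 0.0592 with an estimated correlation). NRF2 antioxidant genes fell, 16 of 22 down and 5 up (adjusted p = 0.0142; adjusted p = 0.087 with an estimated correlation), with Nqo1, a quinone reductase, at −1.84. Nuclear-encoded oxidative phosphorylation genes fell, 19 of 31 down and 1 up with a median of −0.23 (adjusted p = 0.00531; adjusted p = 0.161 with an estimated correlation). The 13 genes encoded by mitochondria had 12 up with a median of 0.46 (adjusted p = 0.000458; adjusted p = 0.3 with an estimated correlation). YAP and SRF targets rose, 18 of 27 up and 5 down (adjusted p = 0.000565; adjusted p = 0.0592 with an estimated correlation). Tubular injury genes had 14 of 22 up and 7 down (adjusted p = 0.0248; adjusted p = 0.146 with an estimated correlation). Clu, clusterin, rose by 2.04 and Havcr1, the injury marker KIM, changed by −1.92. Mesenchymal transcription factors and adhesion genes had 11 of 16 up and 2 down, or 11 and 3 adjusted over the list alone (adjusted p = 0.00414), and immediate early genes had 20 of 29 up and 6 down (adjusted p = 0.00236). The adjusted p was 0.221 for both with an estimated correlation.

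Of the 13244 genes tested in TECs, TGF-β changed 9139, 4513 up and 4626 down, and 1993 of them changed at least 2-fold. Scaling by total counts took the median gene from −0.005 to −0.135 and gave 3298 up and 6169 down, so 34.8% up in place of 49.4%. Besides Csf2, Ccl7 and Nos2, the largest rises were those of Cd83 (5.22), Tnfrsf11b, which encodes osteoprotegerin (5.13), Rassf10 (5.01) and Gna14 (4.47). The largest falls were those of Prss35 (−5.43, or −6.21 without TGF-β replicate 2), the amino acid transporter Slc6a18 (−4.44), the tight junction gene Cldn2 (−4.19), Sprr1a (−4.18) and Zim1 (−3.92, or −4.52 without TGF-β replicate 1). Krt4 had 1 count over the TGF-β libraries, a control-to-TGF-β ratio of 541.5 with a counting interval of 96.8 to 21420. An entry of St6galnac2 changed by −6.51, but the symbol has 2 entries and the other changed by 3.81, so this change is uncertain. Lists of proximal tubule, distal tubule, podocyte, endothelial, fibroblast and epithelial junction markers were not called (adjusted p = 0.0898, 0.32, 0.273, 0.259, 0.0514 and 0.884). This does not mean that their members stayed level, since the median was 0.851 for fibroblast markers and −0.778 for proximal tubule genes. Not called either were ATF4 targets, endoplasmic reticulum (ER) chaperones, p53 targets, apoptosis regulators, heat shock, interferon, ribosomal protein, translation factor, fatty acid oxidation, glycolysis and histone genes.

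The second comparison asks what narciclasine changed in tubular cells held with TGF-β. Inflammatory genes fell, and cell cycle genes rose. Cxcl2, a neutrophil-attracting chemokine (ENSMUSG00000058427), went from 212.1 to 9.34 CPM, a log2 change of −4.50 (SE 0.0555, adjusted p = 1.32e-40). Cxcl1 changed by −4.09 (SE 0.0894), Csf2 by −4.04 (SE 0.053) and Tnf by −3.42 (SE 0.0708), with 3 libraries per group. Col1a2 (ENSMUSG00000029661) changed by −2.43 (SE 0.0568, adjusted p = 5.87e-31) and Col1a1 by −1.38 (SE 0.0426).

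Of 35 inflammatory genes 29 fell and 2 rose, or 29 and 3 adjusted over the list alone, with a median of −1.33 (adjusted p = 1.03e-16; adjusted p = 0.00263 with an estimated correlation). Macrophage and leukocyte markers fell with them, 13 of 14 down with a median of −2.62 (adjusted p = 8.96e-07; adjusted p = 0.0115 with an estimated correlation). Their summed level was 32.0 CPM, below the 49.7 CPM of control cells. Cell cycle genes rose, 38 of 40 up and 1 down with a median of 0.96 (adjusted p = 2.49e-19; adjusted p = 0.00562 with an estimated correlation). Mki67 rose by 1.57 (SE 0.0341) to 189.7 CPM, and Plk1, a mitotic kinase, by 1.65 (SE 0.0586). Ribosome biogenesis genes rose, 29 of 32 up and none down with a median of 0.46 (adjusted p = 6.79e-12; adjusted p = 0.00569 with an estimated correlation). Matrix crosslinking and proteolysis genes fell, 23 of 30 down and 4 up with a median of −0.41 (adjusted p = 2.73e-06; adjusted p = 0.0115 with an estimated correlation), among them Mmp13 at −2.71 and Plat, the tissue plasminogen activator, at −1.35.

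Collagens fell, 14 of 19 down and 1 up with a median of −0.53 (adjusted p = 4.36e-06; adjusted p = 0.0732 with an estimated correlation), and Col3a1 changed by −0.97 (SE 0.107). Matrix glycoproteins fell, 19 of 25 down and 3 up with a median of −0.53 (adjusted p = 8.48e-07; adjusted p = 0.0732 with an estimated correlation). Fn1 changed by −0.29 (SE 0.0246), to 13440 CPM, and Eln, elastin, by −2.14 (SE 0.245). SMAD targets had 18 of 28 down and 3 up, or 18 and 4 adjusted over the list alone, with a median of −0.24 (adjusted p = 0.000105; adjusted p = 0.0204 with an estimated correlation), and Smad7 changed by −0.33 (SE 0.0412). Contractile genes rose, 18 of 26 up and 4 down with a median of 0.23 (adjusted p = 0.000818; adjusted p = 0.0252 with an estimated correlation). In that list Smtn, smoothelin, rose by 0.68, Vim by 0.23, and Des, desmin, changed by −0.76. Acta2 changed by 0.01 (adjusted p = 0.763), Cdh1 by −0.01 (adjusted p = 0.854), and Ccn2 rose by 0.15 (SE 0.0208, adjusted p = 9.01e-08). Tagln rose by 0.09 (adjusted p = 0.00453), a call that ended without TGF-β replicate 2 (adjusted p = 0.058, over alternatives 0.000202 to 0.058). Postn changed by −0.55 (adjusted p = 0.00906), a call that ended with the DESeq2 Wald test (adjusted p = 0.0523) and without narciclasine replicate 2 (adjusted p = 0.0579, over alternatives 0.0065 to 0.0579).

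Stress and metabolic lists were called as well. ATF4 target genes had 23 of 36 down and 4 up with a median of −0.22 (adjusted p = 2.38e-05), p53 targets 16 of 24 down and 3 up with a median of −0.27, apoptosis regulators 16 of 23 down and 4 up with a median of −0.28, and tubular injury genes 14 of 22 down and 6 up with a median of −0.36. The adjusted p of each of these 4 was 0.0252 with an estimated correlation. These calls are not separate, since the lists share members. The p53 list shares Bbc3, Pmaip1, Bax, Fas and Tnfrsf10b with the apoptosis list, and Sesn2 and Ddit4 with the ATF4 list. The injury list shares Icam1, Vcam1, Lcn2, Lif and Ccl20 with the inflammatory list. ER chaperones fell, 13 of 22 down and 1 up (adjusted p = 0.00175; adjusted p = 0.0493 with an estimated correlation). Cholesterol genes fell, 23 of 28 down and 1 up, or 24 and 1 adjusted over the list alone (adjusted p = 1.91e-06; adjusted p = 0.0351 with an estimated correlation), and NRF2 genes had 16 of 22 down and 3 up (adjusted p = 0.00155; adjusted p = 0.028 with an estimated correlation). Heat shock genes rose, 11 of 16 up and 1 down (adjusted p = 0.00289; adjusted p = 0.0352 with an estimated correlation), with Hspb1 at 0.97. The calls of mitochondrially encoded genes, 10 of 13 down with a median of −0.47, glycolysis genes, 13 of 25 down and 5 up, and fibroblast markers, 6 of 9 down (7 adjusted over the list alone), had an adjusted p of 0.197, 0.15 and 0.104 with an estimated correlation. The call of immediate early genes, 14 of 29 down and 9 up (adjusted p = 0.049), had an adjusted p of 0.371 with an estimated correlation. The fibroblast call also ended without TGF-β replicate 2 (adjusted p = 0.0721), and that of immediate early genes without TGF-β replicate 1 (0.0804) or 2 (0.058), or narciclasine replicate 1 (0.105), over alternatives 4.12e-06 to 0.371.

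Narciclasine changed 6921 of 13244 genes in TECs held with TGF-β, 3550 up and 3371 down, and 584 of them at least 2-fold. The split was 4033 up and 2974 down by total counts, and 3395 and 3504 by RLE size factors. The largest rises were those of the kinesin Kif18b (2.05), the cytochrome P450 gene Cyp4a12b (1.97), the kinetochore gene Ndc80 (1.89), EPPK1 (1.88), the primase gene Prim1 (1.83), Cdc20 (1.78) and Dlgap5 (1.78). After the cytokines above, the largest falls were those of Nos2 (−3.36), the macrophage elastase Mmp12 (−3.31) and Cd83 (−3.21, or −3.85 without narciclasine replicate 3). Of the 9139 genes that TGF-β had changed in TECs, narciclasine moved back 4470 (48.9%), 2226 from higher and 2244 from lower, and moved 1071 further the same way. Independent changes would give 2389 genes moved back, and the highest of 20 simulations without a narciclasine effect gave 4. With no narciclasine effect hardly any gene passes the narciclasine test, so these simulations cannot gauge what the shared libraries add among changed genes. Against control, 2270 of the genes moved back were still changed on the same side, 1688 showed no change that passed, and 512 had passed to the other side.

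**Figure D2:**
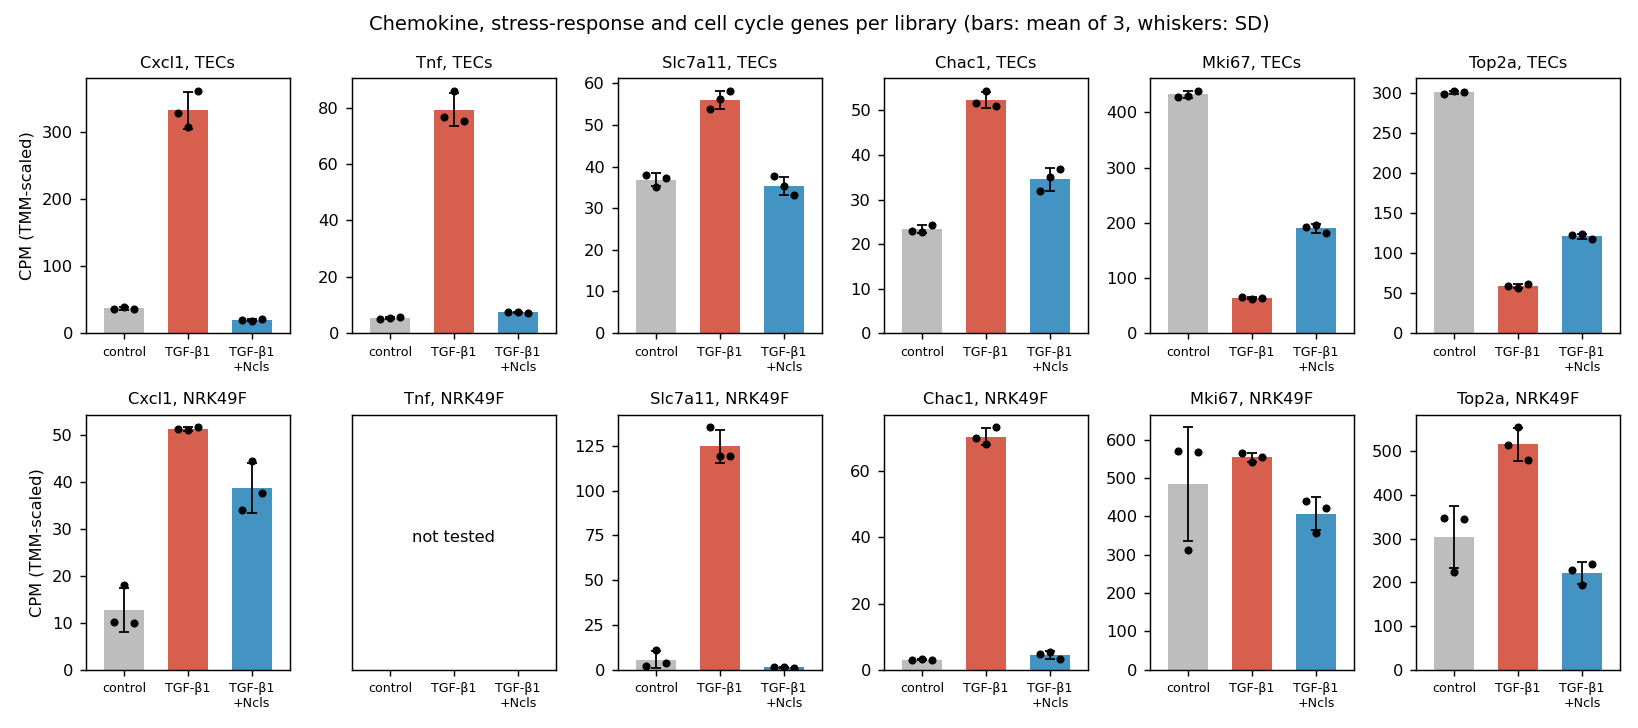
Expression in CPM of the inflammatory genes Cxcl1 and Tnf, the stress genes Slc7a11 and Chac1 and the proliferation genes Mki67 and Top2a, in the groups of TECs and NRK49F (Tnf was not tested in NRK49F). Bars are means of 3 libraries, whiskers are SD and dots are single libraries, and Mki67 in TECs goes from 432.5 to 63.9 and then 189.7 CPM.

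Set against control TECs, cells with TGF-β and narciclasine kept high Fn1 (2.06, SE 0.0257), while Col1a2 (−0.67, SE 0.0658) and Col3a1 (−0.55, SE 0.111) stood below control. Col1a1 stood above control by 1.17 (SE 0.0512). All 40 cell cycle genes were lower than in control, with a median of −1.10 (adjusted p = 2.73e-18; adjusted p = 0.0131 with an estimated correlation). All 28 cholesterol genes were lower, with a median of −0.59 (adjusted p = 1.79e-12; adjusted p = 0.0218 with an estimated correlation). SMAD targets were higher, 21 of 28 up and 5 down (adjusted p = 2.6e-05; adjusted p = 0.0218 with an estimated correlation), and NRF2 genes lower, 18 of 22 down and 3 up (adjusted p = 4.57e-05; adjusted p = 0.0218 with an estimated correlation). Contractile genes had 19 of 26 up and 2 down (19 and 3 adjusted over the list alone) and YAP targets 22 of 27 up and 5 down, each with an adjusted p of 0.022 with an estimated correlation. Inflammatory genes had 22 of 35 up and 10 down (23 and 10 adjusted over the list alone) with a median of 0.48 (adjusted p = 0.029; adjusted p = 0.114 with an estimated correlation), and macrophage markers 8 of 14 down and 1 up with a median of −1.08 (adjusted p = 0.00789; adjusted p = 0.0731 with an estimated correlation). Collagens had 13 of 19 up and 4 down (adjusted p = 0.00208; adjusted p = 0.241 with an estimated correlation). Of 14 lists called against control, 7 up and 7 down, only part are named here, among them all 6 that held with an estimated correlation. In all, 8349 genes differed, 4296 up and 4053 down, 1562 of them at least 2-fold. Scaling by total counts took the median gene from 0 to −0.1 and gave 3174 up and 5433 down, so 36.9% up in place of 51.5%.

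The same treatments in NRK49F ask how kidney fibroblasts respond to TGF-β. Contractile and matrix genes rose, with list calls that ended with an estimated correlation (adjusted p = 0.423 for contractile genes, collagens and matrix glycoproteins). Acta2 went from 3.83 to 208.2 CPM, a log2 change of 5.77 (SE 0.332, n = 3 per group, adjusted p = 3.25e-06), and Tagln, transgelin of the contractile apparatus, from 0.27 to 52.8 CPM, a change of 7.59 (SE 0.383, adjusted p = 1.46e-07). Postn rose by 7.34 (SE 0.107, adjusted p = 1.01e-15) and Ccn2, connective tissue growth factor, by 5.09 (SE 0.524, adjusted p = 0.000128). Without control replicate 2 these rises were 6.43 for Acta2, 8.37 for Tagln and 5.85 for Ccn2. Col1a1 rose by 1.63 (SE 0.0711), from 7599 to 23560 CPM, Col3a1 by 2.06 (SE 0.0618) and Fn1 by 1.51 (SE 0.0746). Chac1, a glutathione-degrading target of ATF4, rose by 4.53 (SE 0.135), and Cdc6, which licenses DNA replication, by 3.56 (SE 0.116).

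Of 34 ATF4 stress response genes tested in NRK49F, 31 rose and 1 fell, with a median of 1.84 (adjusted p = 1.77e-11; adjusted p = 0.15 with an estimated correlation). Among them were the cystine transporter Slc7a11 (4.47, or 5.38 without control replicate 2), the amino acid transporter Slc7a5 (4.46) and Psat1 of serine synthesis (4.36). ER chaperones rose, 20 of 22 up and 1 down with a median of 1.295 (adjusted p = 6.47e-08; adjusted p = 0.15 with an estimated correlation), with Hspa5, the chaperone BiP, at 2.42. Cell cycle genes rose, 31 of 38 up and none down, or 34 adjusted over the list alone, with a median of 1.01 (adjusted p = 4.67e-08; adjusted p = 0.423 with an estimated correlation). Collagens had 13 of 16 up with a median of 1.70 (adjusted p = 2.67e-05), matrix glycoproteins 18 of 23 up and 3 down with a median of 1.61 (adjusted p = 1.98e-05), and contractile genes 16 of 21 up and 2 down with a median of 1.13 (adjusted p = 0.00019). The adjusted p of each of these 3 lists was 0.423 with an estimated correlation. SMAD targets rose, 18 of 26 up and 5 down, or 19 and 5 adjusted over the list alone (adjusted p = 0.000869), as did cholesterol genes, 22 of 27 up and 1 down (adjusted p = 1.72e-05), and ribosome biogenesis genes, 23 of 32 up and 2 down (adjusted p = 1.72e-05). Fatty acid oxidation genes fell, 13 of 21 down and 2 up (adjusted p = 0.0183), with Cpt1a, which brings fatty acids into mitochondria, at −1.84. The adjusted p of these 4 lists was also 0.423 with an estimated correlation.

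**Figure D3:**
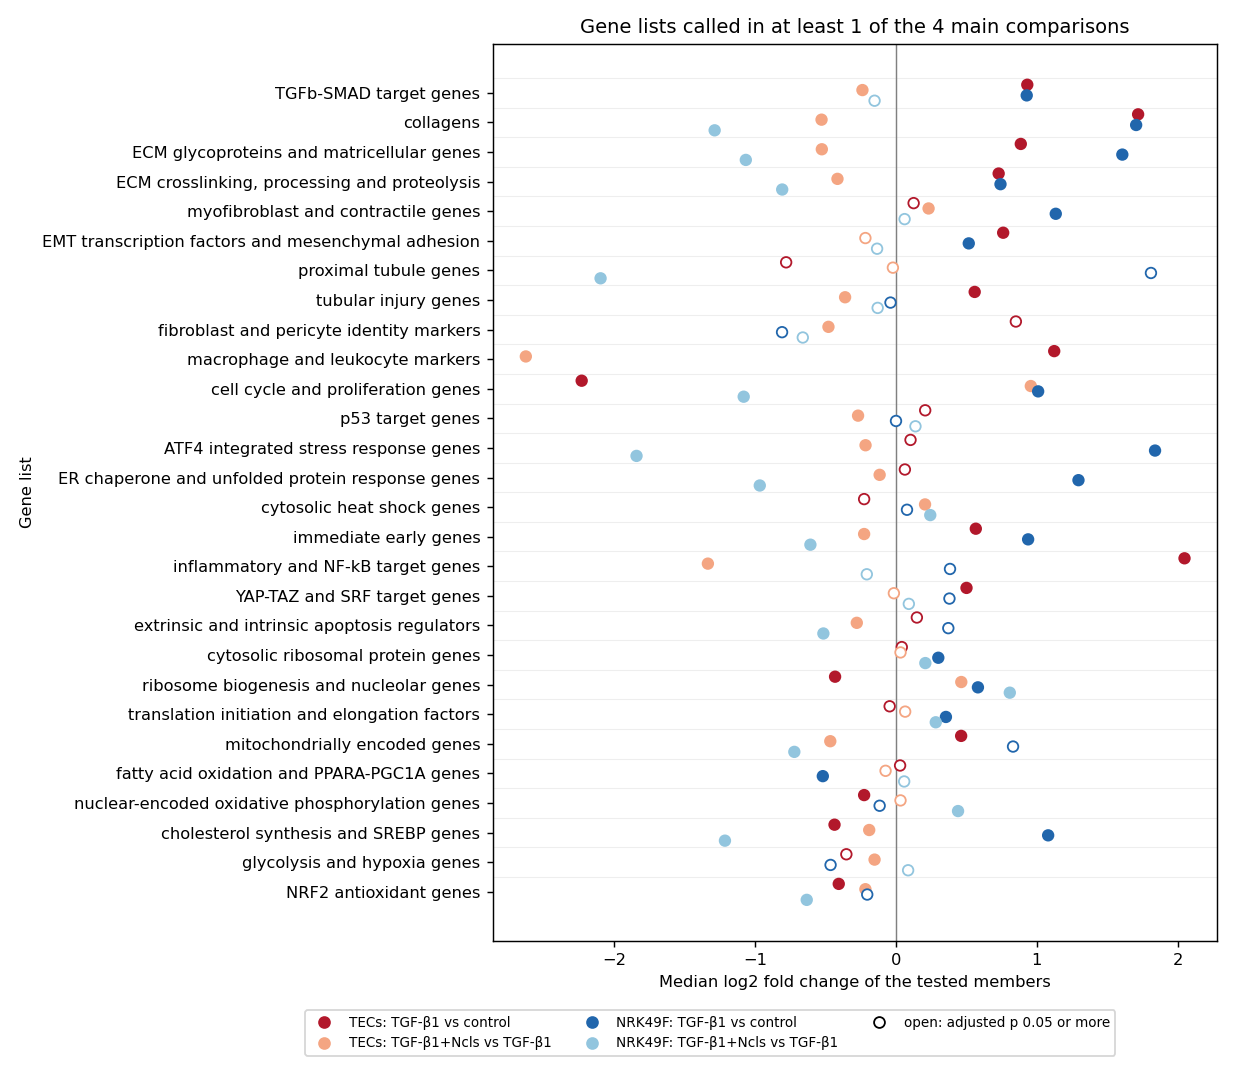
Median log2 fold change of the tested members of each gene list called in at least 1 of the main comparisons, TGF-β against control and TGF-β with narciclasine against TGF-β in TECs and NRK49F. Open points had a camera adjusted p of at least 0.05, and cell cycle genes lie at −2.23 and 0.96 in TECs and at 1.01 and −1.08 in NRK49F.

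Other lists were called in NRK49F as well. Matrix crosslinking genes had 18 of 29 up and 6 down (adjusted p = 0.00952; adjusted p = 0.431 with an estimated correlation). Ribosomal protein genes had 23 of 42 up and 1 down, or 22 and 1 adjusted over the list alone (adjusted p = 0.00152; adjusted p = 0.623 with an estimated correlation). Translation factors had 15 of 23 up and 4 down (adjusted p = 0.0124; adjusted p = 0.423 with an estimated correlation), and Eef2k, the kinase that inhibits elongation, changed by −2.41. Mesenchymal transcription factors had 10 of 16 up and 3 down (adjusted p = 0.049; adjusted p = 0.443 with an estimated correlation), a call that ended with RLE size factors and without any control library or TGF-β replicate 1 (adjusted p = 0.051 to 0.0662, over alternatives 8.66e-06 to 0.443). Immediate early genes had 16 of 26 up and 6 down (adjusted p = 0.0374), a call that ended with RLE size factors (adjusted p = 0.0521, over alternatives 0.000284 to 0.423 with an estimated correlation). Inflammatory genes were not called in NRK49F, with 14 of 28 up and 6 down (adjusted p = 0.111), though Ptgs2, cyclooxygenase, rose by 5.58 and the chemokine Ccl2 by 4.45. Proximal tubule, epithelial, endothelial, fibroblast, injury, p53, heat shock, interferon, YAP, apoptosis, mitochondrially encoded, oxidative phosphorylation, glycolysis and NRF2 lists were not called either.

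TGF-β changed 8216 of 11444 genes in NRK49F, 3862 up and 4354 down, 2645 of them at least 2-fold. Scaling by total counts took the median gene from −0.05 to −0.237 and gave 2965 up and 5497 down, so 35.0% up in place of 47.0%. Srpx2 had 1 count in control and a ratio of 2363 with a counting interval of 423.7 to 93390. Fmod, the collagen-binding fibromodulin, rose by 8.42 (SE 0.323), F13a1, a coagulation factor chain, by 8.42 (SE 0.285) and Lmcd1 by 7.93 (SE 0.225). The ratio was 310.6 for Ctsw (105.9 to 1509) and 262.3 for Rgs14 (72.2 to 2172). Aldh3a1, an aldehyde dehydrogenase, changed by −8.41 (SE 0.181), from 2404 to 7.10 CPM, and Selenbp1 by −6.64 (SE 0.237). Krt16, a keratin, was at 0 in every TGF-β library and at least 79.5-fold lower. The control-to-TGF-β ratio was 735.8 for Pth2r (131.7 to 29100) and 226.1 for Cyp2c11 (40.2 to 8963). An entry each of Ndufa10l1 and Gnas was among the largest changes and another of Ndufa10l1 was among them in the other direction. These symbols have 2 entries each whose counts went opposite ways, so their changes are uncertain. Control libraries stood apart from both treated groups in this, since in 16 of 45 tested pairs of entries with 1 symbol both entries changed at least 2-fold, in opposite directions, against TGF-β, in 14 against TGF-β with narciclasine, and in 0 between the treated groups. Between the treated groups the entries of Calm2 changed in opposite directions by less (0.54 and −1.13). Every value against the NRK49F control carries whatever sets these control libraries apart.

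**Figure D4:**
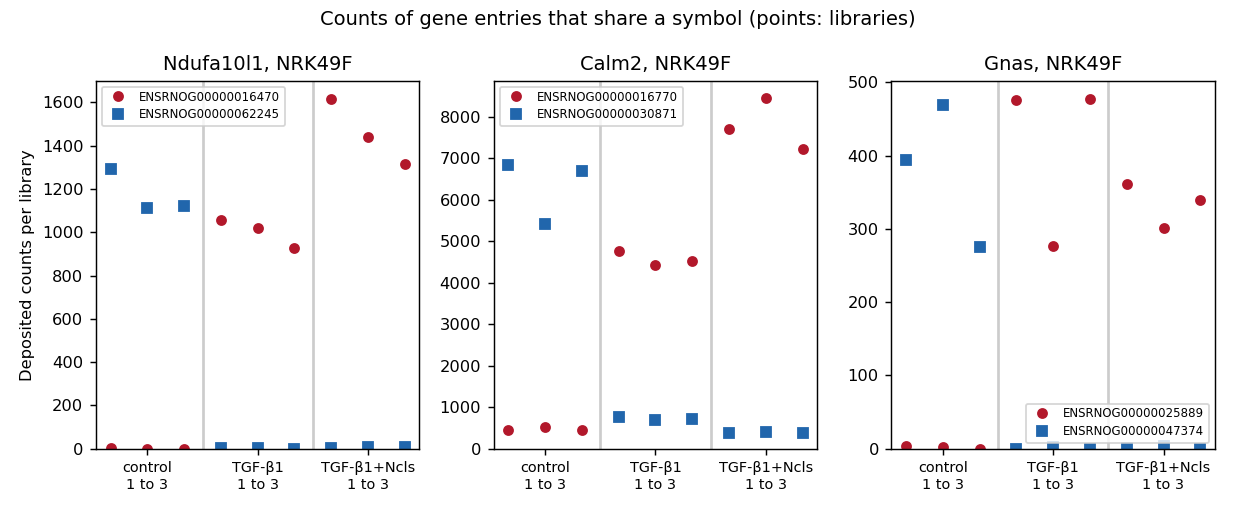
Deposited counts per library (linear axis) for both entries of Ndufa10l1, Calm2 and Gnas in the 9 NRK49F libraries. Each point is a library, and in each pair the entry that holds most counts in control libraries is the lower one in TGF-β and in TGF-β with narciclasine libraries, with log2 changes of 8.84 (9.95 without control replicate 1) and −8.55 for Ndufa10l1, TGF-β against control.

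The next comparison asks what narciclasine changed in fibroblasts held with TGF-β. Stress response, matrix and cell cycle genes fell, and contractile genes as a list were not called. None of these list calls held with an estimated correlation (adjusted p = 0.179 for ATF4 genes, 0.272 for collagens and 0.258 for cell cycle genes). Slc7a11 went from 124.6 to 1.30 CPM, a log2 change of −6.57 (SE 0.522, adjusted p = 3.62e-05). Inhbe, an activin subunit gene, was at 0 in every library with narciclasine, at least 375.6-fold lower than the 22.2 CPM with TGF-β. Col3a1 changed by −1.28 (SE 0.0604, adjusted p = 3.56e-10), Col1a1 by −0.92 (SE 0.0699, adjusted p = 3.41e-08), Fn1 by −0.91 (SE 0.0736) and Postn by −1.93 (SE 0.0799), with 3 libraries per group. For Acta2 (0.55, SE 0.227, adjusted p = 0.0705), Tagln (0.13, adjusted p = 0.577), Ccn2 (−0.29, adjusted p = 0.601), Vim (0.06, adjusted p = 0.399) and Smad7 (−0.19, adjusted p = 0.0751) no change passed the test.

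ATF4 genes fell, 31 of 34 down and none up with a median of −1.84 (adjusted p = 2.81e-13; adjusted p = 0.179 with an estimated correlation), among them Psat1 (−4.34) and the pseudokinase Trib3 (−4.33). ER chaperones fell, 19 of 22 down and 2 up with a median of −0.965 (adjusted p = 1.82e-07; adjusted p = 0.179 with an estimated correlation). Cell cycle genes fell, 35 of 38 down and none up with a median of −1.08 (adjusted p = 6.23e-11; adjusted p = 0.258 with an estimated correlation), among them Cdc6 (−2.72) and Ccne2, cyclin E (−2.12). All 16 collagens fell, with a median of −1.285 (adjusted p = 2.09e-06; adjusted p = 0.272 with an estimated correlation). Matrix glycoproteins fell, 18 of 23 down and 3 up with a median of −1.06, or −0.99 with members at 0 set to their bound (adjusted p = 2.09e-06; adjusted p = 0.279 with an estimated correlation). Spp1, osteopontin, changed by −3.53 and Lum, lumican, by −3.0. Matrix crosslinking genes fell, 23 of 29 down and 1 up with a median of −0.81 (adjusted p = 9.53e-07; adjusted p = 0.272 with an estimated correlation). Cholesterol genes had 24 of 27 down with a median of −1.21 (adjusted p = 7.35e-07; adjusted p = 0.286 with an estimated correlation), with the desaturase gene Scd at −2.61. Ribosome biogenesis genes rose, 30 of 32 up, or 31 adjusted over the list alone, with a median of 0.81 (adjusted p = 3.56e-10; adjusted p = 0.279 with an estimated correlation), with Wdr74 at 1.56. Oxidative phosphorylation genes rose, 21 of 29 up and 1 down with a median of 0.44 (adjusted p = 0.000138; adjusted p = 0.279 with an estimated correlation).

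Further calls in NRK49F were those of NRF2 genes, 16 of 20 down (adjusted p = 1.51e-05; adjusted p = 0.272 with an estimated correlation), and proximal tubule genes, 8 of 8 down with a median of −2.09 (adjusted p = 0.00113; adjusted p = 0.206 with an estimated correlation). The members of the latter list with the largest falls were Acsm2 (−3.81, or −3.20 and −4.55 without narciclasine replicate 2 and 3), the water channel Aqp1 (−2.92) and Ass1 of the urea cycle (−2.68). Ribosomal protein genes had 22 of 42 up and none down (adjusted p = 0.00401; adjusted p = 0.621 with an estimated correlation), and translation factors 16 of 23 up and 4 down (adjusted p = 0.0044; adjusted p = 0.279 with an estimated correlation). Heat shock genes had 11 of 15 up and 2 down, or 11 and 3 adjusted over the list alone (adjusted p = 0.0338; adjusted p = 0.327 with an estimated correlation), a call that ended without TGF-β replicate 1 (adjusted p = 0.0514, over alternatives 0.00015 to 0.327). Immediate early genes had 14 of 26 down and 4 up (adjusted p = 0.0364; adjusted p = 0.279 with an estimated correlation), a call that ended without TGF-β replicate 3 (adjusted p = 0.0564, over alternatives 0.000332 to 0.279). Apoptosis regulators had 13 of 19 down and 3 up (adjusted p = 0.0369; adjusted p = 0.279 with an estimated correlation), a call that ended without the replicate 2 libraries (adjusted p = 0.0694, over alternatives 0.000254 to 0.279). Mitochondrially encoded genes had 5 of 13 down (adjusted p = 0.0378; adjusted p = 0.621 with an estimated correlation), a call that ended without TGF-β replicate 1 (0.115) or 3 (0.083) or narciclasine replicate 2 (0.116), over alternatives 5.05e-05 to 0.621. SMAD targets had 8 of 26 down and 5 up (adjusted p = 0.266) and contractile genes 7 of 21 up and 4 down (adjusted p = 0.513), where the median was 0.06 and the mean −0.007.

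**Figure D5:**
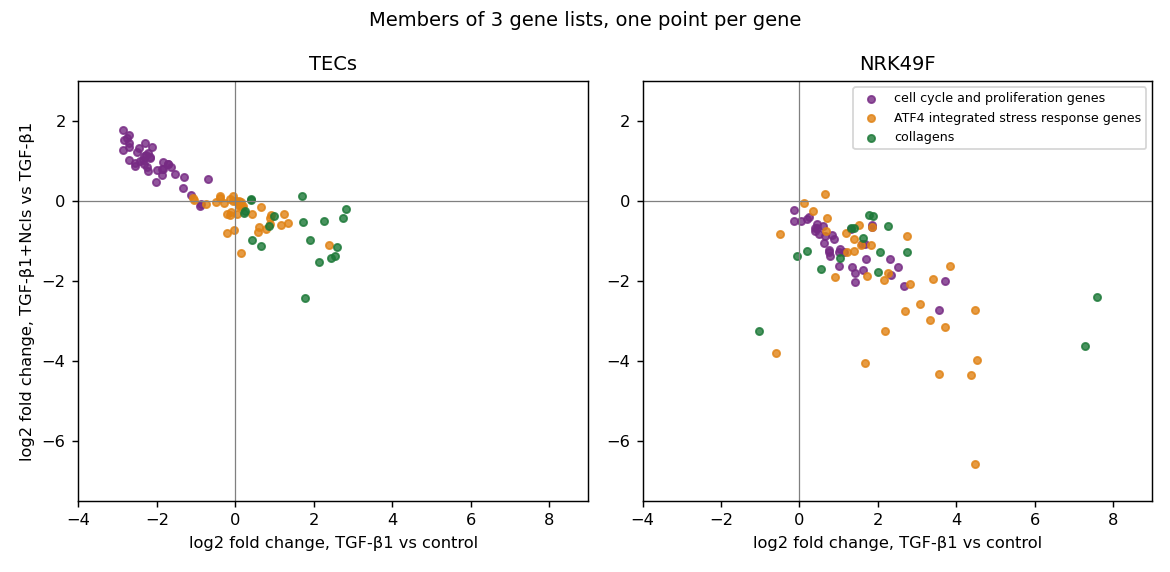
Log2 fold change of TGF-β against control on the horizontal axis and of TGF-β with narciclasine against TGF-β on the vertical axis, with a panel for TECs and a panel for NRK49F. Each point is a tested member of the cell cycle, ATF4 or collagen list, and cell cycle members lie at medians of −2.23 and 0.96 in TECs and 1.01 and −1.08 in NRK49F.

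Narciclasine changed 7178 of 11444 genes in NRK49F held with TGF-β, 3614 up and 3564 down, 1533 of them at least 2-fold. The split was 4120 up and 3060 down by total counts, and 3327 and 3820 by upper-quartile factors. The largest rises were those of the transcription factor Osr1 (3.02), the Wnt agonist Rspo3 (2.87), the interferon-induced Mx2 (2.85), the mitochondrial ribosomal gene Mrpl47 (2.53), Atg14 of autophagy (2.25) and Mrm3 (2.20). Rfxapl1 was at 0 in every TGF-β library and at least 101.9-fold higher with narciclasine (adjusted p = 0.0356), a call that ended without any 1 of the 6 libraries (adjusted p = 0.0578 to 0.0816, over alternatives 0.00012 to 0.143). Beside Inhbe and Slc7a11, the largest falls were those of F13a1 (−8.77), the phagocytic receptor Megf10 (−6.68), Ctsw (−5.04), Tnn, tenascin N (−4.99) and Tfec (−4.94, or −6.23 without narciclasine replicate 1). Of the 8216 genes that TGF-β had changed in NRK49F, narciclasine moved back 4379 (53.3%), 2149 from higher and 2230 from lower, and moved 1249 further the same way. Independent changes would give 2578, and the highest of 20 simulations gave 1, with the same limit as in TECs. Against control, 1643 of the genes moved back were still changed on the same side, 1810 showed no change that passed, and 926 had passed to the other side.

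Set against control fibroblasts, cells with TGF-β and narciclasine kept high Acta2 (6.33, SE 0.332), Tagln (7.72, SE 0.379) and Postn (5.41, SE 0.1). Without control replicate 2 the changes were 6.99 for Acta2 and 8.50 for Tagln. Col1a1 (0.71, SE 0.0697) and Col3a1 (0.77, SE 0.0598) were above control. Ribosome biogenesis genes were higher, 31 of 32 up and 1 down with a median of 1.52 (adjusted p = 3.33e-13; adjusted p = 0.472 with an estimated correlation). Translation factors had 21 of 23 up and 2 down (adjusted p = 3.01e-06; adjusted p = 0.472 with an estimated correlation), and ribosomal protein genes 32 of 42 up, or 34 adjusted over the list alone (adjusted p = 1.03e-06; adjusted p = 0.568 with an estimated correlation). NRF2 genes were lower, 18 of 20 down and 1 up (adjusted p = 3.27e-05; adjusted p = 0.472 with an estimated correlation), with Nqo1 at −2.99. Fatty acid oxidation genes had 15 of 21 down and none up (adjusted p = 0.000441; adjusted p = 0.472 with an estimated correlation). Contractile genes had 16 of 21 up and 3 down (adjusted p = 0.000167), SMAD targets 18 of 26 up and 6 down (adjusted p = 0.0071), YAP targets 15 of 24 up and 4 down, or 15 and 5 adjusted over the list alone (adjusted p = 0.0106) and oxidative phosphorylation genes 18 of 29 up and 1 down (adjusted p = 0.00983). The adjusted p of these 4 lists was 0.567 with an estimated correlation. Cell cycle genes were not called, with 12 of 38 up and 10 down, or 12 and 8 adjusted over the list alone (adjusted p = 0.972), where the median was −0.17, the mean 0.04 and the direction of the test up. In all, 7645 genes differed, 3820 up and 3825 down, 2156 of them at least 2-fold. Scaling by total counts took the median gene from −0.01 to −0.125 and gave 3077 up and 4608 down, so 40% up in place of 50%.

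The cell kinds were then compared directly, on 12161 tested genes of 15957 matched by symbol. The cell cycle list responded in opposite directions, with a median difference of −3.15 in the TGF-β response, TECs minus NRK49F (adjusted p = 1.85e-19; adjusted p = 0.0551 with an estimated correlation). Under added narciclasine the difference was 2.11 (adjusted p = 3.3e-23; adjusted p = 0.0142 with an estimated correlation). All 38 tested members differed in both. ATF4 genes differed by −2.33 in the TGF-β response (adjusted p = 7.07e-09; adjusted p = 0.0647 with an estimated correlation) and by 1.61 under narciclasine (adjusted p = 2.98e-13; adjusted p = 0.0142 with an estimated correlation). Tagln rose by 6.90 log2 units less in TECs (interaction −6.90, SE 0.422, adjusted p = 4.18e-09, or −7.70 without NRK49F control replicate 2) and Postn by 6.40 less (interaction −6.40, SE 0.273), while Col1a1 rose more in TECs (0.89, SE 0.0851). The larger fold change of Col1a1 in TECs started from a far lower level. In this fit Col1a1 went from 37.1 to 218.8 CPM in TECs and from 8484 to 27040 CPM in NRK49F. The TGF-β response differed for 7473 genes, 3807 more positive in TECs and 3666 in NRK49F, and 4611 of them had opposite signs. The narciclasine effect differed for 5701 genes, 3281 more positive in TECs and 2420 in NRK49F. Across genes the log2 changes of both cell kinds had a correlation of 0.048 for TGF-β and 0.164 for narciclasine, and genes are not independent replicates. The tested genes include some hardly expressed in 1 of the cell kinds, so these correlations and the opposite signs do not measure how much response is shared. With at least 1 CPM required in at least 3 libraries of each cell kind, 7062 and 5580 genes differed. The correlations and signs were not worked out for that set.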

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

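The tests of entries that share a symbol, and the tests of macrophage number for the inflammatory genes, were chosen only after those results were seen. For 2 of these tests the reading was also changed after the value was known, as stated below.

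What brought the following results here is a difference between the cell kinds, measured as the interaction of cell kind and treatment (TECs minus NRK49F, log2 units). The TGF-β response differed for 7473 genes and the narciclasine effect under TGF-β for 5701. In the TGF-β response the lists that differed were cell cycle genes (median −3.147), ATF4 genes (−2.326), cholesterol genes (−1.795), contractile genes (−1.298), proximal tubule genes (−1.221), ER chaperones (−1.21), ribosome biogenesis genes (−1.134), translation factors (−0.516), ribosomal protein genes (−0.243), inflammatory genes (0.666) and fatty acid oxidation genes (0.751). With an estimated correlation their adjusted p was, in this order, 0.0551, 0.0647, 0.32, 0.344, 0.146, 0.111, 0.163, 0.213, 0.94, 0.213 and 0.26, so no list call held.

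In the narciclasine effect the lists that differed and held with an estimated correlation were cell cycle genes (2.11, adjusted p = 0.0142), ATF4 genes (1.614, adjusted p = 0.0142), ER chaperones (0.939, adjusted p = 0.0268), inflammatory genes (−0.623, adjusted p = 0.0268) and macrophage markers (−0.855, adjusted p = 0.0177). The macrophage list had too few tested members in NRK49F to be tested there, and 3 of its 13 members differed, so its call rests on genes with little expression in NRK49F. Those that did not hold were proximal tubule genes (1.131, adjusted p = 0.0701 with an estimated correlation), cholesterol genes (0.945, 0.304), matrix glycoproteins (0.807, 0.349), collagens (0.695, 0.281), NRF2 genes (0.443, 0.113), ribosomal protein genes (−0.137, 0.771), translation factors (−0.235, 0.113), oxidative phosphorylation genes (−0.324, 0.165) and ribosome biogenesis genes (−0.342, 0.281).

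Among single genes, the TGF-β response was more positive in NRK49F for Slc47a1 (−9.39), Ifit3 (−8.83), Lipg (−8.17), Lmcd1 (−7.1), Tagln (−6.9), Postn (−6.4), Acta2 (−5.15), Ccn2 (−4.2), Col3a1 (−1.66) and Vim (−1.11). It was more positive in TECs for Krt16 (13.9), Sbk1 (10.6), Tnfrsf11b (7.25), Rspo1 (6.96), Ptk2b (5.31), Col1a1 (0.89), Fn1 (0.81) and Smad7 (0.68). Without NRK49F control replicate 2 the values were −10.41 for Slc47a1, −7.70 for Tagln, −5.83 for Acta2 and −4.98 for Ccn2. Krt16 and Sbk1 rest on NRK49F groups at 0, so the fitted values are neither bounds nor sizes. Other genes had a group near the floor, so the sizes of their interactions are uncertain. In control NRK49F these were Ifit3 and Lipg (0.138 CPM each), Lmcd1 (0.206), Tagln (0.303) and Slc47a1 (0.49). Ptk2b had 0.292 CPM in NRK49F with TGF-β, and Rspo1 0.0663 CPM in control TECs.

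The narciclasine effect was more positive in TECs for Slc7a11 (5.97), Megf10 (4.99), Ctsw (4.87), Aunip (4.25), E2f7 (4.07), Postn (1.44), Cdh1 (1.26), Fn1 (0.68), Col3a1 (0.38) and Vim (0.23). It was more positive in NRK49F for Ccl7 (−3.79), Cxcl1 (−3.63), Nfkbia (−2.36), Mdm2 (−2.27), Slfn2 (−2.12) and Col1a1 (−0.4). In NRK49F with narciclasine, Megf10 (0.429 CPM) and Ctsw (0.628 CPM) were near the floor, so the sizes of their interactions are uncertain. Cdh1 was near it in every NRK49F group (0.225, 0.522 and 0.211 CPM). The Cdh1 call (adjusted p = 0.0382) ended with TMM factors within each species (0.0523), a replicate block (0.0548), total counts (0.0563) and the DESeq2 test (0.0566). It also ended without NRK49F TGF-β replicate 1 (0.383) or 2 (0.0584) and without NRK49F narciclasine replicate 1 (0.0935) or 3 (0.114), over alternatives 0.0111 to 0.383. The Vim call (adjusted p = 0.00504) ended under total counts (adjusted p = 0.0863, over alternatives 5.16e-08 to 0.0863), a setting added after the data were seen.

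The opposite direction of the cell cycle list was weighed first. Its narciclasine interaction of 2.11 was 2.017 under the scaling farthest from TMM, 2.03 without the library that moved it most and 1.99 without the NRK49F replicate 2 libraries, which argues against scaling, a single library and those libraries as the cause. Species and cell kind go together here and no biological explanation was tested, so which of them sets the direction stays open.

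The inflammatory genes of TECs moved together with macrophage markers. In cells with TGF-β and narciclasine the inflammatory median stood 0.475 (SE 0.183) above control and the marker median 1.081 (SE 0.41) below it, with SEs that treat members as independent and an adjusted p of 0.114 and 0.0731 with an estimated correlation. By single genes 22 of 35 inflammatory genes were above control and 10 below, while 1 of 14 markers was above and 8 below. That argues against macrophage number as the whole cause only if the markers follow that number, which was not tested. The fall under narciclasine was −1.303 under the scaling farthest from TMM, against −1.333, which argues against scaling. A loss of macrophages as the cause of the lower markers cannot be told apart from lower expression, and 5 of 14 markers differed from the marker median.

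That count met the bound set first, under which that many markers apart would speak against a loss of cells, and the reading was changed to undecided after the values were seen. Cd68 (−0.97), Csf1r (0.177) and Cd14 (−1.155) are among the 5 and had 7.17, 9.62 and 16.5 CPM in control TECs, so a baseline from other cells could hide a loss. Ptprc (−1.572) and C1qa (−4.777) are the others, and C1qa rests on few counts. Lyz2, with 7.9 CPM in control, fell with the median (−2.824), so such a control level did not by itself keep a marker from falling. Whether other cells give Lyz2 a baseline was not tested, so it does not decide between a loss of cells and lower expression.

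A pair of entries that share a symbol was counted as switched where both changed at least 2-fold with an adjusted p under 0.05, in opposite directions, and this held between control and TGF-β in 16 of 45 NRK49F pairs. In TECs 2 of 8 pairs switched, St6galnac2 and Zc3h11a, both also between control and TGF-β with narciclasine and 0 between the treated groups. Narciclasine moved back 6.2% of the switched NRK49F entries, against 31.2 to 78.1% in 1000 random sets of like change and level, which argues against regulation by TGF-β like that of other genes. Of the switched NRK49F pairs 14 also switched between control and TGF-β with narciclasine, and 0 switched between the treated groups by this rule, where the entries of Calm2 changed in opposite directions (0.542 and −1.133) with 1 of them below 2-fold. Reads assigned differently in the control libraries, or control cells of another stock or genotype, cannot be told apart, because either goes with the control group. With another stock, every NRK49F value against control, the count moved back and the TGF-β interaction would carry that difference too, beyond these pairs, and the same holds for TECs, where the pairs were not tested further.

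The sums of the switched NRK49F pairs changed by a median of 0.266 log2 units. The bound set first for reads assigned differently asked for a value below the lowest of 1000 random sets (0.23), and it was not met. The reading was changed from against to undecided after the value was seen, since the random median was 0.621, the highest 1.186, and 1 of 1000 random sets was as low.

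Other splits of the libraries were counted for each result. For the changed genes of each of the 6 comparisons, 1 of 10 splits reached the real count (9139, 6921, 8349, 8216, 7178 and 7645), and the highest other was 0, or 1 for narciclasine in NRK49F. For called lists 1 of 10 splits reached the real 16, 21, 14, 15 and 17, with the highest other at 14, 20, 12, 12 and 16, and for TGF-β with narciclasine against control in NRK49F 4 of 10 reached the real 9, with the highest other at 15. The 10 splits are too few for a share under 0.05. The other splits called 5 to 20 lists though at most 1 gene changed in any of them. So the number of lists called at the preset correlation hardly sets the real grouping apart. Each of these splits mixes the treatments unequally and keeps part of their difference, so its count is not that of chance either. For genes moved back 2 of 100 splits reached the real 4470 in TECs, with the highest other at 4870, and 1 of 100 reached the real 4379 in NRK49F, with the highest other at 3586. Both highest others kept the control libraries together in the shared place, so they hold the TGF-β difference. Without a narciclasine effect the shared libraries gave at most 4 genes in TECs and 1 in NRK49F over 20 simulations. So low a count follows from a narciclasine test with no true change to find, so it does not weigh the shared libraries. The covariance across genes of the log2 changes of both comparisons can weigh the spread between the shared libraries, and only that. It was −0.2262 in TECs and −0.5004 in NRK49F. The spread of the shared libraries alone gave −0.0171 and −0.0357 in the simulations. A shared group that differs from both others also gives a negative covariance and a high count, as in the TECs split with 4870. So neither shows by itself that narciclasine reversed the TGF-β response. For the interactions 1 of 100 splits reached the real 7473 and 5701, with the highest other at 0, and these splits mixed the treatments in both cell kinds. Mixing puts the treatment difference inside each group and widens its spread, so counts near 0 came with the way the splits were made. The same holds for the 10 splits of changed genes, so neither weighs chance.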

How the results depend on the processing

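The settings that leave out the NRK49F replicate 2 libraries together, or entries that share a symbol, were chosen only after the data were seen. With an absolute log2 change of at least 1 added, the counts of changed genes were 1993, 584 and 1562 in TECs and 2645, 1533 and 2156 in NRK49F, those moved back 382 and 787, and those with an interaction 3114 and 1361, since fewer genes pass both limits. With a correlation estimated per list, 4 and 6 lists were called in TECs against control for TGF-β and TGF-β with narciclasine, and 0, 0 and 0 in NRK49F, also without replicate 2 (0, 0 and 0). By fry, which asks another question, 32, 32 and 28 lists passed in TECs and 28, 26 and 26 in NRK49F. Vim in TECs turned to −0.031 (adjusted p = 0.241) by total counts against control, from 0.10, where the median gene went from −0.005 to −0.135, so the turn comes from a shift shared by all genes.

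Leaving out 1 library gave 8590 to 8930, 6296 to 6576 and 7763 to 7985 changed genes in TECs and 7777 to 8483, 6523 to 6679 and 7077 to 7812 in NRK49F. Called lists were 16 to 18, 19 to 22 and 13 to 15 in TECs and 14 to 16, 15 to 18 and 9 to 11 in NRK49F. Genes moved back were 4106 to 4294 and 3942 to 4816, and interactions 7205 to 7664 and 5359 to 5546. Of 5076 gene values 112 lost their call and 3 gained one, and of 552 list values 15 lost it. The DESeq2 test ended 16 of 836 gene calls, total counts 11 with Vim, and an estimated correlation 67 of 92 list calls. Without the NRK49F replicate 2 libraries 2 of 41 list calls ended, and with an estimated correlation as well all 41.

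Replicate numbers did not pair the libraries in general: 1 of 9 pairs with the same number had a correlation over 0.1 in each cell kind. In both it was TGF-β replicate 2 with narciclasine replicate 2, at 0.166 in TECs and 0.118 in NRK49F. The highest pair with different numbers had 0.139 and 0.103, so an effect shared by these replicate 2 libraries is not excluded. With the number as a block, 9027, 6766 and 8233 genes changed in TECs and 8169, 7167 and 7624 in NRK49F, and 5 gene calls and 1 list call ended. At the depth and spread of these libraries 64% of simulated 1.2-fold changes were found in TECs and 16% in NRK49F, where the coefficient of variation was 0.0812 against 0.0296. Depth alone was not varied.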

Other observations

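Over the tested genes of TECs, log2 change was set against the length of the longest annotated transcript of each gene. The Spearman correlation was 0.084 for TGF-β against control, 0.106 for narciclasine under TGF-β and 0.173 for TGF-β with narciclasine against control. The correlation with the GC content of that transcript was 0.011, −0.009 and 0.015. Genes are not independent replicates.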
